A study of Eohaustorius estuarius with 16 samples.

How the data were processed

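Whole-body RNA extracts of 8 solvent-control and 8 cyfluthrin-exposed amphipods were measured on 1-colour Agilent custom arrays with 15208 spots of 8507 probes (2249 with 1 spot, 6208 with 2, 50 with 10 or 11) and 536 control spots. Groups were taken from the treatment labels and replicate numbers from the sample titles, and arrays with different numbers were treated as separate extracts. The deposited scanner files hold spot intensity made with Agilent Feature Extraction 11.5.1.1 per the file headers, while the submitters' processing notes name version 9.1. Per the file headers the processed intensity is background-subtracted and detrended within each array and not scaled between arrays. The second file is a table of log2 values deposited by the authors, with no description of its scale in the sources used here. Set against the scanner values, it matched quantile-normalised log2 intensities without outlier spots, centred on each probe's median over the 16 arrays (r 0.99983 to 0.99998 per array, slope 1.00), so its scale, centring and direction were settled by that comparison. Its column medians were -0.0044, -0.015, 0.0038, 0.0013, 0.043, -0.035, -0.0062 and -0.021 for control replicates 1 to 8, and -0.0067, 0.021, 0.0053, 0.034, 0.011, -0.017, 0.035 and -0.029 for cyfluthrin replicates 1 to 8. Because the table was centred on each probe, it holds no levels, and it was used only as an alternative.

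The analysis started from the processed intensity. Its log2 was taken, the 336 spots marked as non-uniform or population outliers were left out, each array's 75th percentile over non-control spots was subtracted, and spots of a probe were averaged. A probe was called well above background on an array where at least 50% of its spots carried that mark, and the 7179 probes with that mark on at least 8 of 16 arrays were tested. No spot was saturated. The 75th percentile of the intensity ranged from 165 to 310 and differed between groups by less than the spread of the arrays (two-sided exact permutation p = 0.299). Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Counts at 2-fold use an absolute log2 difference of at least 1. Whole profiles and per-array measures were compared with exact permutation tests over all splits of the 16 arrays. Figures were drawn with matplotlib 3.10.9.

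The groups, tests, thresholds, filter, most alternatives and the rule for naming probes were fixed before the data were examined. The rule names, where probes carry no gene names, the 2 probes with the largest rise and the 2 with the largest fall among those that passed. The 20 gene lists fixed at the same time matched 0 probes, since the files pair probes only with contig numbers, and the tests of gene lists were therefore not run. The comparison was tested on simulated data with the real spread, 200 of 7179 probes changed and 8 arrays per group. It recovered 52% of probes changed by 0.5 on the log2 scale, 82% at 1, 94% at 2 and 94% at 3, with 6 false calls among 167. With 4 arrays per group it recovered 10%, 58%, 96% and 96%. The simulated noise was normal and independent between probes and arrays. These rates therefore do not cover probes that vary together or an array that lies with the other group.

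Slide numbers and positions come from the file headers. Each of the 2 slides was scanned once, held 4 control and 4 exposed arrays, and both groups occur in each of its 4 rows and 2 columns taken over the slides. The rows were not balanced. On slide 2, row 3 held only control replicates 3 and 8, and row 4 only cyfluthrin replicates 5 and 8. Alternatives were quantile normalisation, a median shift, normexp background correction (offset 50), the authors' table, other filters, outlier spots kept, other variance models, array weights, slide, row, column or replicate number as a block, each slide alone, each array left out, and other thresholds. Normexp used the median pixel intensity of each spot in place of the mean. Fits without the array labelled control replicate 3 in combination with other settings, normexp included, normexp with each array's median background, and the processed signal plus the offset alone, were added after seeing the data. For the distance and the detected probes, the fit without that array and each slide alone were added too, and for the spread the fit without that array. No array was left out of the main fit.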

Results

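The estuarine amphipod Eohaustorius estuarius, a burrowing crustacean used in sediment toxicity tests, was exposed for 10 days to sediment spiked with cyfluthrin at a nominal 1.6 µg/kg or to sediment spiked with solvent only. Cyfluthrin is a pyrethroid insecticide, a class that acts on voltage-gated sodium channels. Whole-body RNA of 8 control and 8 exposed amphipods was labelled with Cy3 and hybridised to a custom oligonucleotide array, 1 array per extract. These 16 arrays come from 1 of the 6 laboratories of a comparability study that received extracts prepared in a single laboratory, and arrays of the other laboratories were not analysed here. Each of the 8507 probes was designed on a separate assembled contig, and the files pair no contig with a gene name, so the results are given for probes. Between 6675 and 7422 probes per array were well above background, and 7179 probes met the filter for testing. The number of arrays limits the precision of every value below.

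The main comparison asked which transcripts differed in abundance between exposed and control amphipods. Of the 7179 probes tested, 620 (8.64%) passed at a limma adjusted p under 0.05, of which 248 rose and 372 fell with cyfluthrin. The share of rises, 40% here, was 46.4% with quantile normalisation (295 rose and 341 fell), 49.5% in the authors' table (314 rose and 320 fell) and 53.6% with normexp (81 rose and 70 fell). Most changes were small, with a median of 1.42-fold among the probes that rose and 1.42-fold among those that fell. Larger changes were mostly rises, clearly so only from 4-fold up. At least 2-fold, 56 probes rose and 37 fell, at least 4-fold 38 rose and 7 fell, and at least 8-fold 13 rose and 0 fell. The excess of rises at 2-fold was nearly lost with array weights (63 rose and 62 fell). It was also small without the array labelled control replicate 3 (67 and 63), where 42 rose and 7 fell at least 4-fold. All 8 exposed arrays lay above the control median at 231 of the 248 probes that rose, and below it at 339 of the 372 that fell. Of the 620 probes, 586 were well above background on all 16 arrays, and 0 were not well above background in a whole group. With an offset of 50 added to the processed signal before the log2, which compresses weak signals, 544 probes passed, 505 of them among the 620, with 37 rising and 18 falling at least 2-fold, 18 and 3 at least 4-fold, and 0 at least 8-fold. With normexp, which has the same offset and uses median pixel intensity, 151 probes passed, 133 of them among the 620, with 36 rising and 11 falling at least 2-fold, 15 and 1 at least 4-fold, and 1 and 0 at least 8-fold. Of the 620 probes, 54 had the opposite sign with normexp, among them 6 of the 56 that rose at least 2-fold, and 0 of the 54 passed there. With normexp on each array's median background 494 passed, 462 of them among the 620, with 35 and 18 at least 2-fold, 16 and 3 at least 4-fold, and 0 at least 8-fold. There the ranges of control replicates 3 and 5 were 4.22 and 4.80, and 2 of the 620 probes had the opposite sign. With the replicate number as a block 365 probes passed, 328 of them among the 620. Same-numbered arrays shared a slide, and the median r of their deviations was 0.26, against -0.046 for other pairs. The main fit does not use the numbers as pairs, and pairing stays open. With the array row as a block, which was not balanced between the groups, 429 passed, 411 of them among the 620. Before adjustment 1727 probes had p under 0.05 in the main fit, where 359 would be reached by chance alone.

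**Figure D1:**
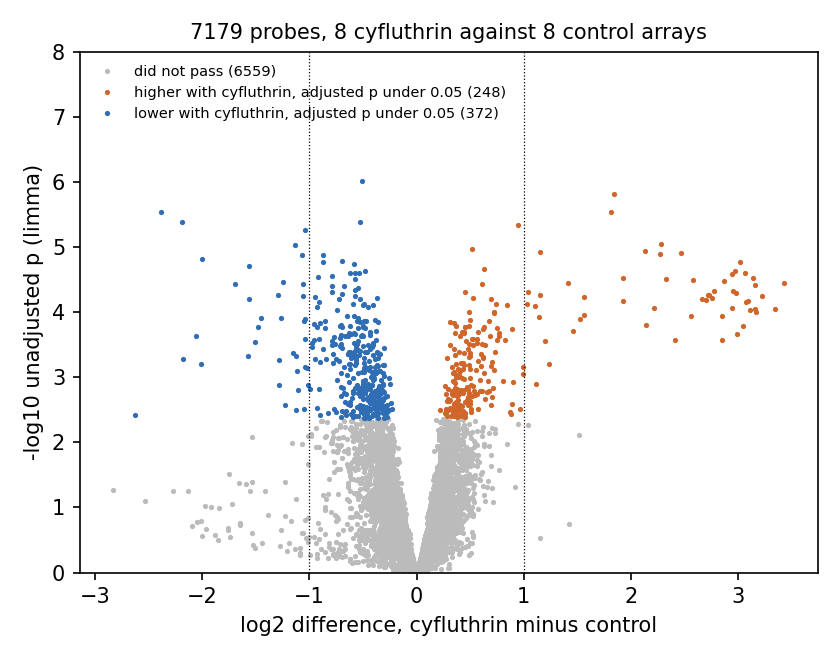
Log2 difference between the 8 cyfluthrin and the 8 control arrays (horizontal axis) against the negative log10 of the unadjusted limma p (vertical axis) for 7179 probes. Orange points are the 248 probes that rose and blue points the 372 that fell at adjusted p under 0.05, dotted lines mark 2-fold changes, and the probes beyond 4-fold are mostly rises (38 against 7).

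The array labelled control replicate 3 lay among the exposed arrays at the probes that changed most. The 56 probes that rose at least 2-fold had a mean level on that array of 0.46 (log2 relative to the array's 75th percentile). The other 7 controls lay between -3.26 and -1.72, and the 8 exposed arrays between -0.36 and 0.76. The 37 probes that fell at least 2-fold had a mean level of -1.15 on that array, between 0.15 and 0.81 on the other controls, and between -1.52 and -0.86 on the exposed arrays. Without that array 1062 probes passed, 470 of them higher and 592 lower with cyfluthrin, and 619 of the 620 probes were among them, all 619 in the same direction. Other settings kept fewer of the 620. With the offset of 50, 1443 probes passed, 569 of them among the 620. With normexp these counts were 472 and 364, and with normexp on the median background 1326 and 563. In the processed signal without that array 67 probes rose and 63 fell at least 2-fold, against 43 and 27 with the offset of 50, 39 and 24 with normexp and 42 and 28 with normexp on the median background. The fitted rise was at least 8-fold at 28 probes, but 10 of these were not well above background on at least 1 of the 7 controls, 3 of them on all 7. It was at least 8-fold at 5, 1 and 2 probes in those settings. The groups did not overlap at 30 of the tested probes with all arrays, where chance gives 1.12. Without the array labelled control replicate 3 this was 320, and without any other single array 31 to 73, where chance gives 2.23. Leaving out single arrays for this count was chosen after the values had been seen. Leaving out control replicate 1, control replicate 8 or cyfluthrin replicate 5 lowered the count of probes that passed to 399, 388 and 408.

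**Figure D2:**
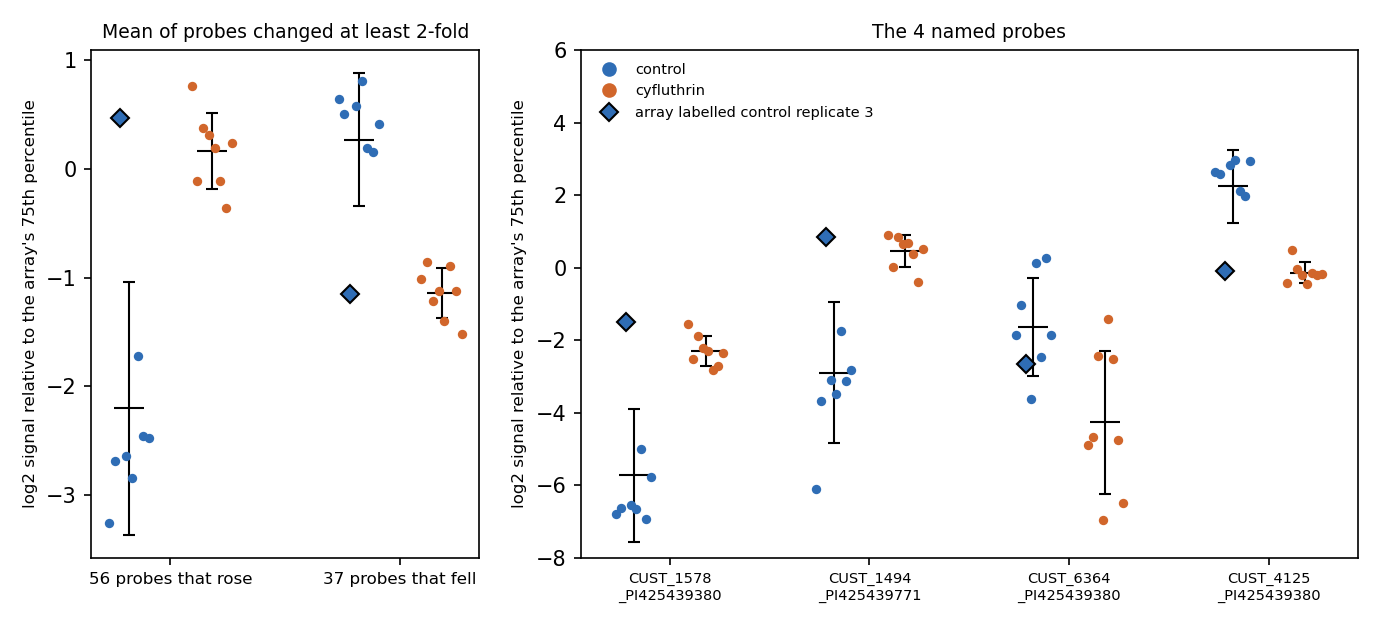
Log2 signal relative to the array's 75th percentile (vertical axes) on each control array (blue) and cyfluthrin array (orange), with the mean and SD of 8 arrays per group, for the mean of the probes that changed at least 2-fold (left) and for the 4 named probes (right). The diamond is the array labelled control replicate 3, which lies at 0.46 among the exposed arrays for the 56 probes that rose and at -1.15 among them for the 37 that fell.

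In the processed signal, the largest log2 rise among the probes that passed was that of CUST_1578_PI425439380, on contig 6676. Its log2 level was -5.73 ± 1.83 in controls and -2.30 ± 0.42 in exposed amphipods (SD, n = 8 each), a difference of 3.43 ± 0.61 (SE; limma adjusted p = 0.00595). It was well above background on 3 of 8 control arrays and on all 8 exposed arrays, so its fold of 10.8 rests on control levels near background. With the offset of 50 alone the fold was 1.81 (adjusted p = 0.0144), with normexp 1.36 (adjusted p = 0.624) and with normexp on each array's median background 1.70 (adjusted p = 0.0164). Over all alternatives the adjusted p ran from 6.54e-08 to 0.624. Probe CUST_1494_PI425439771, on contig 6271 and well above background on 7 of 8 control arrays, rose 10.2-fold, from -2.90 ± 1.95 to 0.45 ± 0.44 (SD, n = 8 each), with a log2 difference of 3.35 ± 0.65 (SE) and a limma adjusted p of 0.00695. Its fold was 4.17 with the offset alone and 3.34 and 3.61 with the normexp settings, under all of which it exceeded that of CUST_1578_PI425439380. All 8 exposed arrays lay above the control median at both probes. The array labelled control replicate 3 was the highest control at each, at -1.49 and 0.84. Without it CUST_1494_PI425439771 rose 14.7-fold, or 3.92-fold and 4.47-fold with the normexp settings. CUST_1578_PI425439380 was then well above background on 2 of 7 controls, and its fold ran from 1.63 and 1.93 with the normexp settings to 16.4 in the processed signal.

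In the processed signal, the largest log2 fall among the probes that passed was that of CUST_6364_PI425439380, on contig 2742, from -1.64 ± 1.36 in controls to -4.27 ± 1.97 in exposed amphipods (SD, n = 8 each). Its log2 difference of -2.63 ± 0.78 (SE) passed narrowly, at a limma adjusted p of 0.0459. It was well above background on 5 of 8 exposed arrays, 7 of the 8 lay below the control median, and in 24 of 37 alternative settings the call was lost, with adjusted p from 0.0264 to 0.517. It was 6.20-fold lower in the processed signal, and 1.92-fold, 2.03-fold and 1.84-fold lower with the offset alone, normexp and normexp on the median background. In those settings CUST_4125_PI425439380 was 4.54-fold, 4.34-fold and 4.45-fold lower, so the order of both falls turned. Probe CUST_4125_PI425439380, on contig 2561, fell from 2.24 ± 1.01 to -0.14 ± 0.29 (SD, n = 8 each). Its log2 difference was -2.38 ± 0.34 (SE), 5.21-fold lower, with a limma adjusted p of 0.00465 that 7 probes shared, and all 8 exposed arrays lay below the control median. Without the array labelled control replicate 3 it was 6.56-fold lower.

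The 16 arrays lay on 2 slides, each with 4 control and 4 exposed arrays. With the slide as a block 630 probes passed, 94 of them changed at least 2-fold. Within slide 1 139 probes passed. Within slide 2, which holds the array labelled control replicate 3, limma called 0 probes (696 with unadjusted p under 0.05, where chance gives 359), and 188 once that array was left out. The difference in the exposure effect between slides passed at 0 probes (110 with unadjusted p under 0.05, limma interaction term). As 110 is below the 359 of chance, this test may be conservative here, and it does not show that the slides agree. CUST_1578_PI425439380 differed by 3.99 within slide 1 and 2.87 within slide 2 on the log2 scale, CUST_1494_PI425439771 by 3.89 and 2.80, CUST_6364_PI425439380 by -2.86 and -2.40, and CUST_4125_PI425439380 by -2.62 and -2.14. Once the array labelled control replicate 3 was left out, the slide 2 differences of these probes were, in the same order, 4.08, 3.84, -2.83 and -2.87.

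Whole profiles asked whether exposure separated the arrays over all tested probes. The mean distance (1 minus Pearson's r) was 0.00805 larger between groups than within them (exact permutation p = 0.0219, one-sided, 6435 splits). Within slide 1 the difference was 0.00756 (exact p = 0.171, one-sided) and within slide 2 0.00145 (exact p = 0.343, one-sided), so it did not pass within either slide of 8 arrays. Median r was 0.952 among controls, 0.954 among exposed arrays and 0.947 between groups, across probes, which are not independent replicates. The highest r of all 120 pairs, 0.992, was that of the array labelled control replicate 3 with cyfluthrin replicate 3. Of the first 5 principal components, component 2 (19.3% of the variance) differed between the groups (two-sided exact permutation p = 0.0087, 0.0435 after Benjamini-Hochberg over the 5), by -25.6 within slide 1 (exact p = 0.0286, the smallest that 35 splits allow) and -24.4 within slide 2 (exact p = 0.143). Component 1 (29.7%) did not pass (exact p = 0.20).

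**Figure D3:**
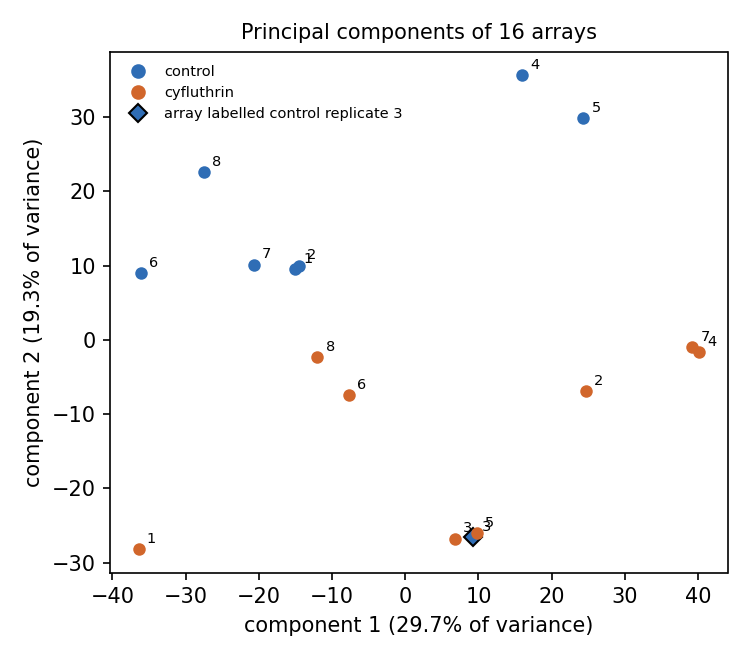
Scores of the 16 arrays on component 1 (29.7% of the variance, horizontal axis) and component 2 (19.3%, vertical axis), with the replicate number beside each point. Exposed arrays (orange) lie below 0 on component 2 and control arrays (blue) above 0, except the array labelled control replicate 3 (diamond), which lies at -26.6 beside cyfluthrin replicates 3 and 5.

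No difference in detection between the groups passed. Controls had 7179 ± 236 and exposed amphipods 7098 ± 228 probes well above background (SD, n = 8 each), a difference of -81.5 (two-sided exact permutation p = 0.493), which was -138 within slide 1 (exact p = 0.514) and -25 within slide 2 (exact p = 0.886). Across probes, the median SD over the 8 arrays of a group was 0.26 (log2) in controls and 0.28 in exposed amphipods. Over 5254 tested probes with duplicate spots, the median SD between arrays of a group was 0.28, which was 2.63 times the 0.11 between spots of the same array. Of 59 array control probes, limma called 0 (1 with unadjusted p under 0.05).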

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

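The values of single arrays were screened by a rule fixed beforehand, and the counts over other splits of the arrays were planned; all tests of the array labelled control replicate 3 were chosen after its position had been seen. Of 24 sets of 8 arrays screened, 5 held an array far from the other 7. Chance gives about 5% of independent sets. These sets overlap, as the named probes are among those changed at least 2-fold, which were chosen from the same data. The 5% is thus no test of the count. Of the 5, 4 concern the array labelled control replicate 3. Its mean log2 level was 0.46 over the 56 probes that rose at least 2-fold, with the nearest other control at -1.72, and -1.15 over the 37 probes that fell, with the nearest at 0.15. It stood at -1.49 for CUST_1578_PI425439380 (nearest other control -5.01) and at -0.081 for CUST_4125_PI425439380 (nearest 1.96). The remaining value was 0.49 for CUST_4125_PI425439380 in cyfluthrin replicate 2, with the nearest other exposed array at -0.04. The header of the array labelled control replicate 3 lists 0 for the slope of its spike-in fit, and its 75th percentile intensity of 165 was the lowest of the 16.

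An exposure score was formed that is 0 at the control mean and 1 at the exposed mean, from probes chosen without the array scored and without both arrays numbered 3. The array labelled control replicate 3 scored 1.11, the other controls -0.12 to 0.22 and the exposed arrays 0.82 to 1.09, so no exposed array was out of place as a swap between the groups would need. The slide does not account for it, since the highest score of the other 3 controls on that slide was 0.094. On 208 probes that varied between the other 14 arrays without following exposure, it differed from cyfluthrin replicate 3 by a median of 0.15 (log2). Duplicate spots of such probes on the same array differ by 0.10, and the nearest of the other 119 pairs by 0.43. On these probes that ratio of 0.341 argues against RNA of a further animal, whether exposed or responding like one. Still, 14 of the 208 differed by more than 1 between the 2 arrays, against 41 or more in every other pair. Over all tested probes the contrast was weaker, with a median difference of 0.12 against 0.18 for the nearest other pair. A candidate explanation that stays open, as a hypothesis, is that RNA of cyfluthrin replicate 3 was on both arrays; where that would have happened was not tested, and arrays of the same extracts from the other laboratories were not analysed here.

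Chance was weighed with 100 splits of the 16 arrays into 8 and 8, the real one included. As many as 620 probes were reached by 2 of the 100 splits, and as many as 93 probes changed at least 2-fold by 2 of the 100. Both shares lie below the 0.05 fixed beforehand. They rest on few of the possible splits, and the real split was not the highest drawn, so chance is unlikely but not excluded. The highest other split gave 1177 probes, 123 of them at least 2-fold. It differs from the real split by exchanging the array labelled control replicate 3 with cyfluthrin replicate 1, which points to a structure of the samples. Of the 100 splits 96 gave 0 probes, and the split by slide, taken separately, gave 15. In 100 random divisions into 4 control and 4 exposed arrays, the part that held the array labelled control replicate 3 gave 0 to 12 probes and the other part 103 to 919.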

How the results depend on the processing

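The settings that leave out the array labelled control replicate 3 together with another choice, normexp with each array's median background, and the processed signal plus 50, were chosen after seeing the data. So were the settings without that array for the distance, the detected probes and the spread, and the slides taken alone for the distance and the detected probes. Of 40 alternatives for the count of 620 probes, 25 stayed within 1.5 times. Outside that range lay normexp (151, with 53.6% rises against 40%), array weights (1168), slide 1 alone (139), slide 2 alone (0, limma, 696 with unadjusted p under 0.05), thresholds of 0.01 (171) and 0.10 (1044), and fits without the array labelled control replicate 3 in slide 2 (188), with quantile normalisation (1076), without the filter (959) and with the slide block (1036). With the replicate number as a block 365 probes passed. Same-numbered arrays deviated together (r over 0.1) in 5 of 8 pairs (-0.19 to 0.52). Of 16 arrays 6 correlated best with their own number, so pairing stays open. Leaving out each array gave 388 to 1062 probes, and 388 to 683 apart from control replicate 3. Slides and thresholds change the number of arrays or the bar itself, and the cause was not tested for the others.

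Of 40 alternatives for the 93 probes changed at least 2-fold, 35 stayed within 1.5 times. The others were normexp (47, with 76.6% rises against 60.2%), slide 2 alone (0), normexp with the array's median background (53), the processed signal plus 50 (55) and no filter without the array labelled control replicate 3 (143). Leaving out each array gave 82 to 130. Planned normexp narrowed the range from the 5th to the 95th percentile to 1.32 and 3.05 (log2) on control replicates 3 and 5, against 7.30 and 7.86 in the main values, and moved the median SD to 0.52 in controls and 0.16 in exposed arrays. The distance between groups kept its direction in 8 alternatives and passed in 6 (to 0.0122, without control replicate 3), but not within slide 1 (0.00756) or slide 2 (0.00145). The lower number of detected probes (-138 to -25) passed in none. Of the named probes, CUST_6364_PI425439380 lost its call in 24 of 37 alternatives, CUST_1578_PI425439380 in 2, CUST_1494_PI425439771 in 2 and CUST_4125_PI425439380 in 1 of 38. With the offset of 50 alone, normexp, and normexp on the median background, the fold went from 10.8 to 1.81, 1.36 and 1.70 for CUST_1578_PI425439380, from 10.2 to 4.17, 3.34 and 3.61 for CUST_1494_PI425439771, from 6.20 to 1.92, 2.03 and 1.84 for CUST_6364_PI425439380, and from 5.21 to 4.54, 4.34 and 4.45 for CUST_4125_PI425439380. No sign of a named probe changed, while 54 of the 620 probes turned with normexp, 0 of them passing. On all arrays 2 of the 620 turned with normexp on the median background. Without the array labelled control replicate 3, 2 turned with normexp and 8 with normexp on the median background. The planned gene list tests were not run. Signal near background limits probes such as CUST_1578_PI425439380 in controls.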

Other observations

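All tests in this part were chosen after the values had been seen. Once the array labelled control replicate 3 was left out, 7 probes that rose were not well above background on any of the 7 remaining controls, and 5 of them were well above background on all 8 exposed arrays. Counting controls at the lowest signal well above background, these 7 probes rose at least 1.58-fold to 4.47-fold. The median of the 56 probes that rose at least 2-fold was 6.17-fold with all arrays and 8.31-fold without that array, and that of the 37 that fell was 2.38-fold and 2.64-fold. With an offset of 50 alone on all arrays the median of the risers was 2.72-fold. With normexp on all arrays these medians were 2.49-fold and 1.90-fold, with 6 of the 56 risers turned to a fall. With normexp on the median background they were 2.59-fold and 1.96-fold, with 0 of the 56 turned.

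The 56 probes that rose at least 2-fold also varied together between animals of the same group. After the group means were removed, and without the array labelled control replicate 3, their median pairwise correlation over arrays was 0.425, while 1000 random sets of probes with like spread had a median of 0.029 and reached at most 0.180 (p = 0.001, the smallest they can give). The 37 probes that fell had 0.249, against at most 0.201. As a hypothesis, the probes that rose may share a state that differs between animals. Contigs of the same transcript under neighbouring numbers do not account for it, with 1 neighbouring pair among the 56 and up to 4 in random sets; contigs of the same transcript with distant numbers stay open.

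At 117 of the 7599 probes well above background on at least 3 arrays, the 16 arrays fell into separate high and low levels, with a gap of at least 1.5 (log2) and at least 3 arrays on each side. The most frequent division, at 20 probes, set control replicates 4 and 5 and cyfluthrin replicates 2, 4 and 7 apart from the other 11 arrays, and independent reordering of the arrays at each probe gave at most 3 probes for any division in 1000 draws, which argues against sequence variants that differ independently between animals at each contig. The slide does not separate these arrays, as 3 lie on slide 1 and 2 on slide 2. The mean log2 level of the 20 probes was -3.93, -4.35, -2.74, -3.94 and -4.10 on those 5 arrays. It was 1.34, 0.76, -0.09, 1.95, 1.11 and 0.36 on control replicates 1, 2, 3, 6, 7 and 8, and 2.29, -0.17, 0.35, 0.71 and 0.13 on cyfluthrin replicates 1, 3, 5, 6 and 8. The same 5 arrays had the highest scores on component 1, from 15.9 to 40.2, with 9.80 as the highest of the others. Of the 20 probes 0 passed the exposure comparison, and no biological explanation was tested, since the labels give no sex, size or moult stage.

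The second most frequent division, at 14 probes, set the 8 exposed arrays and the array labelled control replicate 3 apart from the other 7 controls. Probes that passed were not more often neighbours by contig number. Of 6007 neighbouring pairs 26 passed in the same direction, where random orders gave a mean of 23.3.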
